A study of Homo sapiens with 16 samples.

How the data were processed

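Gene expression was measured in SH-SY5Y, a human neuroblastoma cell line that takes on neuron-like features when treated with retinoic acid (RA). Total RNA was labelled with biotin and hybridised to Affymetrix arrays, 1 RNA sample per array and 1 colour. The 16 arrays came from 13 biological samples in 4 groups. The undifferentiated group held 6 samples (6 arrays). The RA 4-day group held 4 samples (4 arrays), the RA 7-day group 2 samples (4 arrays) and the RA plus BDNF group 1 sample (2 arrays). Per the labels, undifferentiated replicates 1 to 4 belonged to batch 1, and undifferentiated replicates 5 and 6 and all treated samples to batch 2.

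The deposited values were log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with RMA, which corrects background, applies quantile normalization between arrays and summarises the probes of a probe set, and with the affy package. The versions of both are not given in the sources used here. Each array held 49495 probe sets, of which 102 were controls. Array medians lay between 4.87 and 4.93 and array SDs between 2.30 and 2.41 on the log2 scale. The arrays did not share 1 distribution: SDs were 2.30 to 2.32 on undifferentiated and 2.36 to 2.41 on treated arrays. Quantile normalization reduces a shift shared by most genes, so the size of such a shift was not estimated. RMA values of weakly expressed genes are compressed toward the background, so fold changes of such genes are understated. The values carry no detection call, and the number of arrays limits the precision.

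Probe sets were named through the platform's probe table, in which 45284 probe sets had 1 gene symbol and 1333 had several. The other 2878 probe sets, controls included, had no entry. Symbols were updated through entrez_id against RefSeq genes of assembly GRCh38.p14, which matched 45214 of the 45284 probe sets. No genome build is named in the sources used here for the array, so no coordinates are given. Probe sets with several symbols were left out. A gene was represented by its probe set with the highest mean over all arrays, which left 18244 genes, 11826 of them with more than 1 probe set. All value columns were mapped to samples, and 0 were left unmapped.

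Arrays of 1 biological sample were averaged with avearrays. A linear model with a mean per group and a batch term was fitted to the 13 samples with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual and 4.66 prior degrees of freedom. All p-values from limma were two-sided and adjusted by the Benjamini-Hochberg method over the 18244 genes of a comparison, with a threshold of 0.05. 5 contrasts were tested: each treated group against the undifferentiated group, RA 7 days against RA 4 days, and RA plus BDNF against RA 7 days. All treated samples were in batch 2, so with the batch term each contrast against undifferentiated cells rested on undifferentiated replicates 5 and 6 for its size and on all samples for its spread. The single RA plus BDNF sample was assumed to vary like the other groups. The labels number the replicates without stating that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

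The tests, the samples in each fit, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, for each comparison, the 6 largest rises and the 6 largest falls past the test, and for each list past its test the 3 members with the smallest adjusted p in the direction of the list. CYP26A1, RARB, DHRS3, RET, NTRK2, MKI67 and TH were always named. Where under 5 genes passed, the 5 largest moderated t values in each direction were named as values. Further members of the lists are named in the text as examples.

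The 32 gene lists covered retinoic acid targets, HOX clusters, DNA replication, G2 and mitosis, ribosome biogenesis and MYC targets, cholesterol synthesis, fatty acid synthesis, immediate early genes, BDNF and MAP kinase responses, and neurotrophin and GDNF family genes. They also covered neurofilament and growth cone, synaptic vesicle, dense core granule, postsynaptic, ion channel, catecholamine, cholinergic and axon guidance genes. Cell type lists covered noradrenergic transcription factors, mesenchymal-type neuroblastoma genes, and Schwann and glial genes. The rest covered p53 targets, apoptosis, the unfolded protein response, glycolysis, oxidative phosphorylation, lysosome and autophagy, Parkinson disease genes, oxidative stress defence, interferon-stimulated genes, Notch and Wnt. Each list was tested against all other genes with camera from limma at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 160 tests of 32 lists and 5 comparisons. Each test was repeated with a correlation estimated from the residuals. Members past the test were counted with adjustment over all genes and adjusted over the list alone.

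Control probe sets were summarised per array in Python 3.11.15 and R, and compared between groups with two-sided exact permutation tests. Genes beyond the largest exogenous control shift at 4 days were regressed on ACTB 3' minus 5' and on 18S between samples of the same treated group, a test added after the data were seen. The alternatives covered the batch term, the treatment of technical replicates, a filter on dim probe sets, the choice of probe set, the normalization, the variance model, a replicate block and leaving out each biological sample in turn. Cyclic loess, a covariate for mesenchymal-type genes and a few further settings were added after the data were seen.

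The model was tested on simulated data for 18244 genes with known changes. In each comparison 67, 67 and 66 genes were changed by 0.5, 1 and 2. The noise was independent, with a spread per gene that was equal in all groups. The spread of the RA plus BDNF sample was thus assumed, not tested. In the data up to 37.2% of genes passed and treated arrays shared differences in control probe sets, so the shares below need not hold there. At a log2 change of 0.5, 1 and 2 it recovered 58.2%, 97.0% and 100% of the changed genes for RA 4 days against undifferentiated. The shares were 41.8%, 98.5% and 100% for RA 7 days, and 20.9%, 82.1% and 100% for RA plus BDNF, each against undifferentiated. They were 41.8%, 95.5% and 100% for RA 7 days against RA 4 days, and 22.4%, 89.6% and 100% for RA plus BDNF against RA 7 days. False calls numbered 8 of 178, 5 of 165, 4 of 139, 10 of 168 and 14 of 155 calls in these comparisons.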

Results

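Expression was measured on 16 Affymetrix arrays of SH-SY5Y, a human neuroblastoma line. Undifferentiated cells (6 samples) were grown for 7 days in medium with 10% fetal bovine serum. For differentiation the serum was lowered to 1% and 10 µM all-trans RA was added, for 4 days (4 samples) or 7 days (2 samples, each on 2 arrays). In a further protocol brain-derived neurotrophic factor (BDNF), a ligand of the receptor kinase TrkB, was added at 50 ng/ml from day 4 and cells were taken at day 7 (1 sample on 2 arrays). Treated and undifferentiated cells thus differed in serum as well as in RA, and the RA 4-day cells also in days of culture. Values below are means ± SD of RMA log2 values or log2 differences ± SE from limma, with the fold change where given. All adjusted p are from limma or, for gene lists, from its camera test.

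The first comparison addressed what 4 days of RA in low serum did to expression (4 against 6 samples). The largest rises included genes that handle RA itself. CYP26A1, a cytochrome P450 that degrades RA, averaged 12.48 ± 0.19 after RA and 4.76 ± 1.41 in undifferentiated cells, a difference of 7.57 ± 0.78 or 190-fold (adjusted p = 1.86e-05). CYP26B1, a related RA-degrading enzyme, rose by 7.35 ± 0.76 (163-fold, adjusted p = 2.03e-05), and DHRS3, which reduces retinaldehyde, by 5.95 ± 0.37 (61.9-fold, adjusted p = 3.84e-07). NTRK2, which encodes TrkB, went from 3.23 ± 0.15 to 8.33 ± 0.12, a rise of 5.09 ± 0.12 (34-fold, adjusted p = 6.17e-11). RARB, an RA receptor, rose by 3.54 ± 0.10 (11.6-fold) and RET, a receptor of GDNF family ligands, by 2.33 ± 0.12 (5.02-fold). GDF10, a ligand of the BMP family, rose by 5.95 ± 0.16 (62-fold) and POU2AF2 by 5.03 ± 0.31 (32.7-fold). The size of 4 of these rises rested on single undifferentiated samples: without replicate 5 and without replicate 6 the differences were 5.96 and 9.18 for CYP26A1, 5.62 and 9.07 for CYP26B1, 5.06 and 6.84 for DHRS3, and 4.31 and 5.75 for POU2AF2.

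The largest falls at 4 days were in NELL1 (-3.66 ± 0.31), the angiotensin receptor gene AGTR1 (-3.29 ± 0.20), the growth regulator MYC (-3.05 ± 0.39), SLITRK6 (-2.93 ± 0.19) and the transcription factor genes SOX6 (-2.76 ± 0.16) and LMO4 (-2.69 ± 0.22). MYC averaged 5.81 ± 0.74 after RA and 8.83 ± 0.31 before (8.3-fold lower, adjusted p = 8.9e-05). MKI67, a marker of cycling cells, differed by 0.14 ± 0.09 (adjusted p = 0.229), though 2 of its 6 probe sets passed, both higher (0.35 and 0.66), and TH, which encodes tyrosine hydroxylase, by -0.04 ± 0.10 (adjusted p = 0.764). The fold sizes depended on the probe set: averaged over all probe sets of a gene, the difference was 3.65 for CYP26B1, 3.28 for DHRS3, 2.31 for NTRK2, -2.07 for NELL1, -1.05 for SOX6, -1.29 for LMO4, -0.72 for BYSL, 1.04 for INHBA and 0.66 for SNAP25. With probe sets of the x and s suffix left out, which can match several transcripts, NELL1 differed by 0.06.

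**Figure D1:**
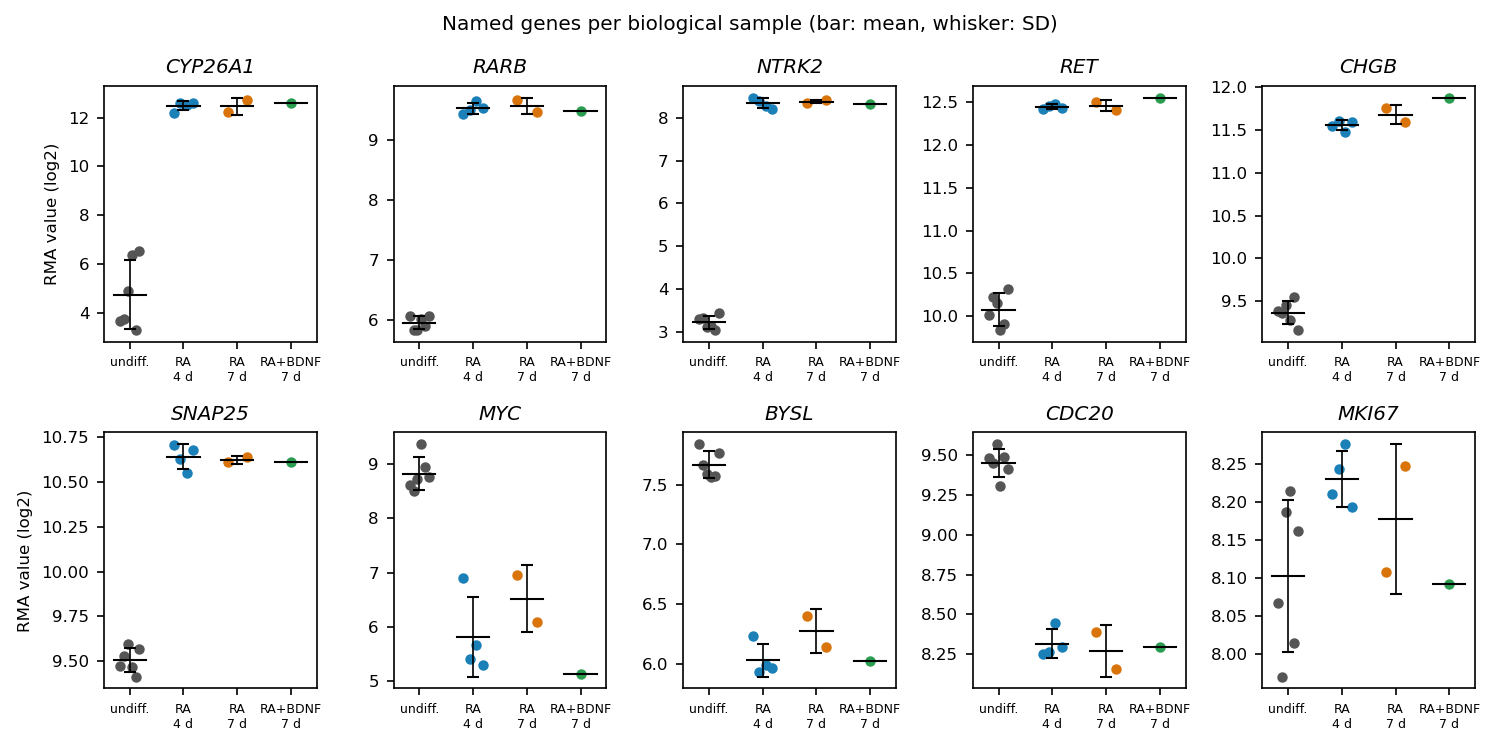
RMA log2 value (vertical axis) of 10 named genes in each biological sample of the 4 groups, with arrays of a sample averaged, bars at the mean and whiskers of 1 SD (none for the single RA plus BDNF sample). CYP26A1 lay between 3.30 and 6.52 in undifferentiated samples and between 12.2 and 12.7 in treated ones, while MKI67 overlapped between groups.

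In all, 6786 of 18244 genes (37.2%) passed the test at 4 days, 3360 higher and 3426 lower, and 640 of them changed over 2-fold. The balance depended on scaling, with 3668 higher and 2779 lower after each array was centred on its median and 2758 and 3404 after quantile normalization again. The median SE of a gene was 0.11. Of 25 measured RA target genes, 14 rose, 1 fell and 10 did not pass (14 and 2 adjusted over the list alone). The list stood above other genes (median 0.73, camera adjusted p = 7.93e-07), also with an estimated correlation (adjusted p = 0.0351). Its median was 2.33 among genes above the median level, 0.36 over all probe sets of a gene and 0.31 without probe sets of the x and s suffix. It was the only list past the test with an estimated correlation in any of the 5 comparisons, where it held for each treated group against undifferentiated cells. ADD3, a cytoskeletal adducin gene of that list, rose by 1.97.

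Genes of ribosome biogenesis and MYC targets moved down almost as a block at 4 days. Of 37 measured, 0 rose, 33 fell and 4 did not pass (0 and 33 adjusted over the list alone), with a median of -0.68 (adjusted p = 7.29e-13, but adjusted p = 0.266 with an estimated correlation). The nucleolar genes BYSL (-1.64), NOP16 (-1.65) and WDR12 (-1.04) fell with MYC. Of 43 G2 and mitosis genes, 2 rose, 12 fell and 29 did not pass (2 and 12 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.147). Of 45 DNA replication genes, 11 rose, 4 fell and 30 did not pass (10 and 4 adjusted over the list alone, adjusted p = 0.147).

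Several groups of neuronal genes stood higher at 4 days. Of 37 synaptic vesicle genes, 15 rose, 1 fell and 21 did not pass (15 and 2 adjusted over the list alone, adjusted p = 1.58e-03, adjusted p = 0.432 with an estimated correlation). They included the SNARE gene SNAP25 (1.15), the synapsin gene SYN1 (0.79) and PCLO (0.94), which encodes a scaffold of the presynaptic active zone. Of 27 dense core granule and neuropeptide genes, 11 rose, 1 fell and 15 did not pass (11 and 1 adjusted over the list alone, adjusted p = 2.06e-03, adjusted p = 0.197 with an estimated correlation). Chromogranin B (CHGB, 2.21), the neuropeptide galanin (GAL, 1.5) and the neurosecretory protein gene VGF (1.46) were among them. Of 41 neurofilament, microtubule and growth cone genes, 18 rose, 3 fell and 20 did not pass (19 and 3 adjusted over the list alone, adjusted p = 1.76e-03, adjusted p = 0.548 with an estimated correlation). DPYSL3 (2.47, and 3.11 or 1.84 without undifferentiated replicate 5 or 6), BASP1 (1.12) and the motor protein gene KIF1A (0.83) rose, though of 5 KIF1A probe sets past the test 2 were higher and 3 lower and their mean differed by -0.11. Of 35 BDNF and MAP kinase responsive genes, 10 rose, 2 fell and 23 did not pass (10 and 2 adjusted over the list alone, adjusted p = 9.2e-03, adjusted p = 0.493 with an estimated correlation). INHBA rose by 1.85 and DUSP6, a phosphatase acting on ERK, by 1.67, before any BDNF was added.

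Lysosome and autophagy genes also rose at 4 days: 17 of 29 rose, 0 fell and 12 did not pass (20 and 0 adjusted over the list alone, adjusted p = 8.08e-07, adjusted p = 0.266 with an estimated correlation). SQSTM1, an autophagy receptor, rose by 1.01, WIPI1 by 0.80 and prosaposin (PSAP) by 0.69. Of 27 glycolysis and hypoxia genes, 15 rose, 1 fell and 11 did not pass (17 and 1 adjusted over the list alone, adjusted p = 2.29e-04, adjusted p = 0.521 with an estimated correlation). P4HA2 (1.33), ALDOC (0.85) and P4HA1 (0.63) led them. Of 27 p53 target and growth arrest genes, 9 rose, 1 fell and 17 did not pass (9 and 1 adjusted over the list alone, adjusted p = 0.0264, adjusted p = 0.546 with an estimated correlation). The cell cycle inhibitors CDKN1B (1.1), CDKN2D (0.89) and RB1 (0.76) rose. Of 22 cholesterol synthesis genes, 8 rose, 0 fell and 14 did not pass (9 and 0 adjusted over the list alone, adjusted p = 0.0315, adjusted p = 0.311 with an estimated correlation), among them TM7SF2 (1.11), IDI1 (0.85) and STARD4 (0.76). Of 18 Schwann and glial genes, 0 rose, 8 fell and 10 did not pass (0 and 8 adjusted over the list alone, adjusted p = 0.0394, adjusted p = 0.43 with an estimated correlation). NGFR (-0.57), GFAP (-0.46) and ALDH1L1 (-0.38) fell, from means of 5.49, 5.77 and 4.42, while high GC background probe sets at 5.74 differed by -0.38 on the same arrays. Under other settings of scaling, probe set or blocking the cholesterol, p53 and Schwann and glial lists were lost, with adjusted p from 0.0605 to 0.321, 0.0601 to 0.2 and 0.0674 to 0.194, and the BDNF and MAP kinase list was lost among genes above the median level (0.158). Averaged over all probe sets RB1 (0.35) and GFAP (-0.17) did not pass, and with probe sets of the x and s suffix left out GFAP turned to 0.04, STARD4 did not pass (0.81, adjusted p = 0.0807) and SQSTM1 differed by 0.49. CDKN2D differed by 0.50 without undifferentiated replicate 6. Without undifferentiated replicate 6 the neurofilament (adjusted p = 0.322), BDNF and MAP kinase (0.116), p53 (0.336) and Schwann and glial (0.0556) lists did not pass, and without replicate 5 the cholesterol (0.0939) and Schwann and glial (0.0706) lists did not.

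**Figure D2:**
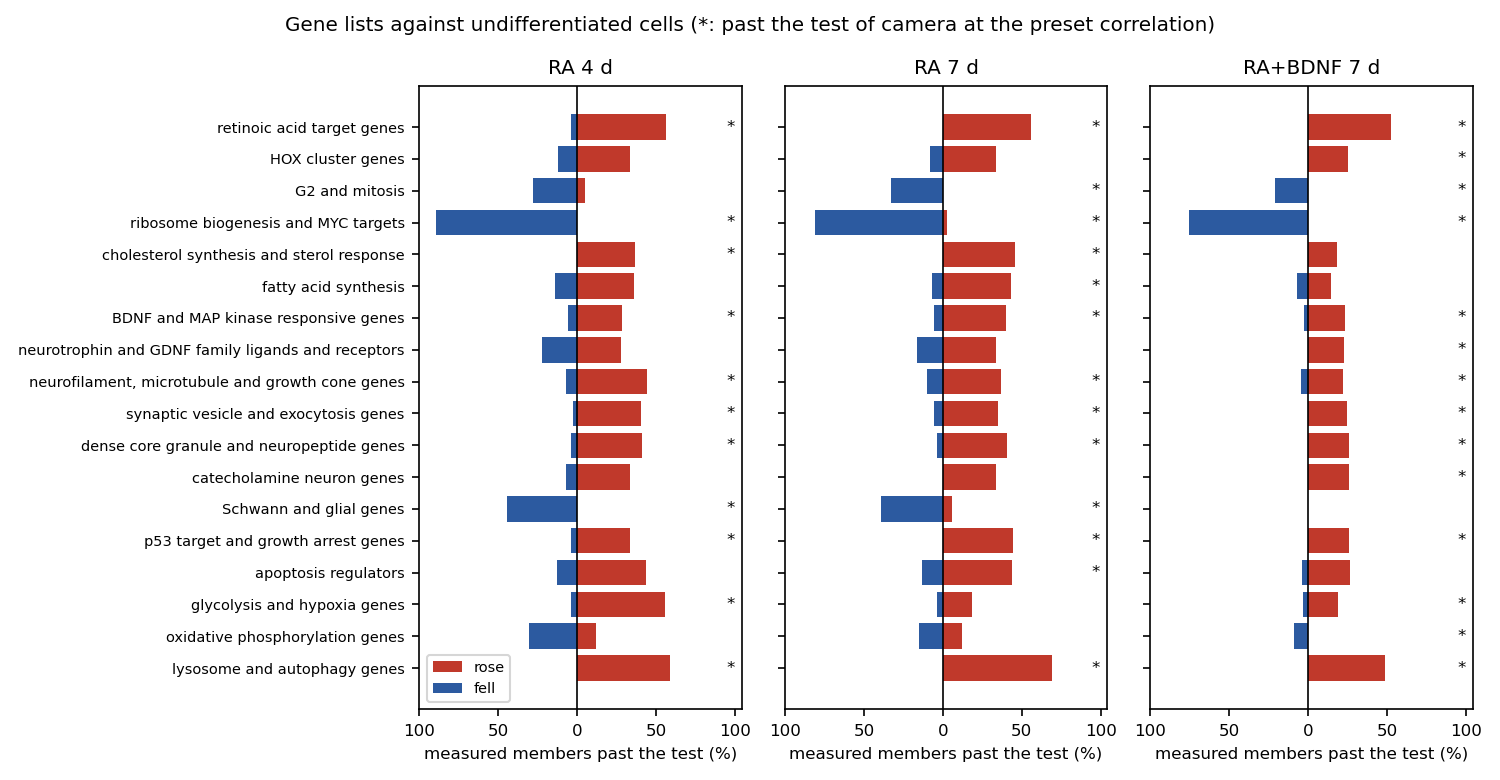
Share of the measured members of 18 gene lists (percent, horizontal axis) that rose (red, right) or fell (blue, left) past limma's test in each treated group against undifferentiated cells, with a star where the list passed camera's test at the preset correlation. Of 37 ribosome biogenesis and MYC targets, 33, 30 and 28 fell, and of 25 RA targets, 14, 14 and 13 rose.

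The treated arrays also differed from the undifferentiated ones in control probe sets, which hold no cellular message or report on RNA quality. The mean of 18 hybridisation control probe sets was 10.53 ± 0.04 in undifferentiated and 9.84 ± 0.10 in RA 4-day samples, a difference of -0.70 (exact permutation p = 0.00476, two-sided, the smallest that 210 splits allow, adjusted over 9 measures 0.00536). Within batch 2 alone the exact p was 0.0667, the smallest that 15 splits allow. Background probe sets of high GC content averaged 5.74 and 5.35. The 3' minus 5' signal of ACTB, a sign of RNA degradation, was 1.93 ± 0.04 and 2.62 ± 0.43 (exact permutation p = 0.00476, within batch 2 0.2), and 3.25 on the array of RA 4-day replicate 1. That of GAPDH was 0.67 and 0.82 (exact permutation p = 0.0524, within batch 2 0.4). 18S ribosomal RNA probe sets averaged 10.09 ± 0.22 and 8.20 ± 1.2, a difference of -1.89 (exact permutation p = 0.00476, within batch 2 0.133), with 6.49 in RA 4-day replicate 1, and poly-A controls differed by -0.80. Hybridisation controls, high GC background, 18S and ACTB parted every treated from every undifferentiated array, the same grouping as the rises and falls above, while poly-A controls, 28S and GAPDH overlapped. 28S ribosomal RNA averaged 8.11 in undifferentiated and 7.44 in RA 4-day samples (exact permutation p = 0.00476, within batch 2 0.0667), but 8.71 with RA plus BDNF. The largest shift of any of 82 exogenous control probe sets was 1.69 at 4 days, which is less than that of 18S and measures no RNA quality. Of the 6786 genes, 156 changed by more than that (125 higher, 31 lower), among them CYP26A1, NTRK2, RARB, RET, CHGB, DPYSL3, MYC and NELL1, and 6630 by less, among them BYSL, SNAP25, SQSTM1 and NGFR.

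**Figure D3:**
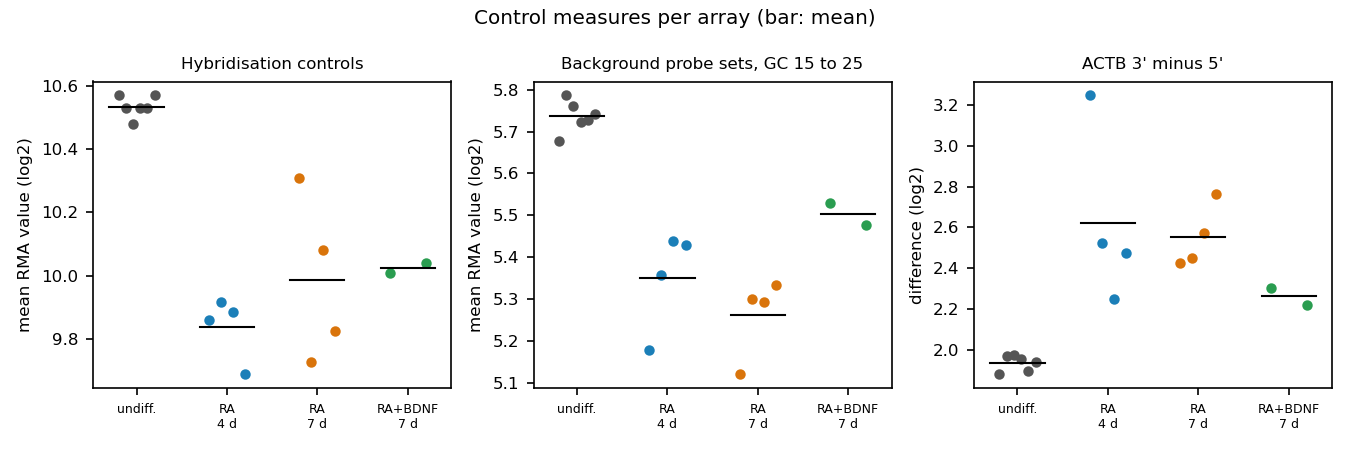
Mean log2 value of hybridisation controls and of background probe sets, and the log2 difference between 3' and 5' ACTB probe sets (vertical axes), on each of the 16 arrays by group, with bars at the mean. Hybridisation controls lay between 10.48 and 10.57 on undifferentiated arrays and between 9.69 and 10.31 on treated arrays.

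Within batch 2 alone, with 2 undifferentiated samples, 5669 genes passed at 4 days. With batch as a random block 11465 passed.

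The second comparison addressed the state after 7 days of RA (2 against 6 samples). CYP26B1 (7.56 ± 0.88, 189-fold), CYP26A1 (7.55 ± 0.90, 187-fold, adjusted p = 7.91e-05), GDF10 (6.73 ± 0.18, 106-fold), DHRS3 (6.08 ± 0.43, 67.8-fold), TGM2 (5.58 ± 0.34, 47.8-fold) and POU2AF2 (5.35 ± 0.35, 40.8-fold) rose most. TGM2 encodes transglutaminase, an RA-responsive enzyme. NTRK2 rose by 5.13 ± 0.13 (35.1-fold, adjusted p = 2.28e-10), RARB by 3.58 ± 0.12 and RET by 2.34 ± 0.14. AGTR1 (-4.06 ± 0.24), SLITRK6 (-3.85 ± 0.22), the orphan nuclear receptor gene NR4A3 (-3.48 ± 0.74, adjusted p = 0.00363), NELL1 (-3.32 ± 0.36), SOX6 (-3.15 ± 0.19) and RORB (-2.91 ± 0.21) fell most. MKI67 (0.09 ± 0.10, adjusted p = 0.522) and TH (-0.07 ± 0.12, adjusted p = 0.689) did not pass. Without undifferentiated replicate 5 and without replicate 6 the differences were 5.94 and 9.16 for CYP26A1, 5.84 and 9.29 for CYP26B1, 5.19 and 6.97 for DHRS3, 4.88 and 6.28 for TGM2, and 4.63 and 6.07 for POU2AF2. Without RA 7-day replicate 1 and without replicate 2 NR4A3 differed by -2.53 and -4.42. Averaged over all probe sets the difference was 3.76 for CYP26B1, 3.29 for DHRS3, 2.64 for NTRK2, 1.70 for TGM2, -1.49 for NR4A3, -1.98 for NELL1, -1.25 for SOX6 and -1.93 for RORB. With probe sets of the x and s suffix left out TGM2 differed by 0.45, NR4A3 by -0.01 (adjusted p = 0.988) and NELL1 by 0.00.

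At 7 days 6097 genes (33.4%) passed, 3033 higher and 3064 lower, 727 of them over 2-fold. RA targets again stood high: 14 rose, 0 fell and 11 did not pass (14 and 0 adjusted over the list alone, adjusted p = 9.92e-07, adjusted p = 0.0351 with an estimated correlation). Of 37 ribosome biogenesis and MYC targets 1 rose, 30 fell and 6 did not pass (1 and 32 adjusted over the list alone, adjusted p = 9.9e-10, adjusted p = 0.369 with an estimated correlation), with BYSL at -1.39, WDR43 at -1.31 and WDR12 at -0.93. Of 43 G2 and mitosis genes 0 rose, 14 fell and 29 did not pass (0 and 17 adjusted over the list alone, adjusted p = 3.13e-03, adjusted p = 0.521 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell by 1.18, CENPF by 1.09 and HMMR by 0.72. Of 18 Schwann and glial genes 1 rose, 7 fell and 10 did not pass (1 and 7 adjusted over the list alone, adjusted p = 0.0409, adjusted p = 0.432 with an estimated correlation). NGFR (-0.79), GFAP (-0.70) and OLIG2 (-0.67) fell, where the high GC background averaged 5.26 against 5.74, though GFAP differed by 0.07 without probe sets of the x and s suffix.

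Of the neuronal lists, 4 passed at 7 days, while postsynaptic (adjusted p = 0.733, median -0.13), ion channel (0.939, -0.16), axon guidance (0.561, -0.14), cholinergic (0.47, -0.06) and catecholamine genes (0.186, -0.07) did not. Of 37 synaptic vesicle genes 13 rose, 2 fell and 22 did not pass (14 and 4 adjusted over the list alone, adjusted p = 3.01e-03, adjusted p = 0.456 with an estimated correlation), with SYNGR3 at 1.45, SNAP25 at 1.14 and SYN1 at 0.81. Of 27 dense core granule genes 11 rose, 1 fell and 15 did not pass (11 and 1 adjusted over the list alone, adjusted p = 1.58e-03, adjusted p = 0.197 with an estimated correlation), with CHGB at 2.33, GAL at 1.72 and VGF at 1.28. Of 41 neurofilament and growth cone genes 15 rose, 4 fell and 22 did not pass (20 and 4 adjusted over the list alone, adjusted p = 4.43e-04, adjusted p = 0.522 with an estimated correlation), with DPYSL3 at 2.75 (3.39 or 2.12 without undifferentiated replicate 5 or 6), BASP1 at 1.22 and KIF1A at 0.75 (-0.08 as the mean of its probe sets). Of 35 BDNF and MAP kinase responsive genes 14 rose, 2 fell and 19 did not pass (14 and 2 adjusted over the list alone, adjusted p = 1.29e-03, adjusted p = 0.43 with an estimated correlation), with INHBA at 1.77 and DUSP6 at 1.74.

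Of 29 lysosome and autophagy genes 20 rose at 7 days, 0 fell and 9 did not pass (20 and 0 adjusted over the list alone, adjusted p = 1.37e-08, adjusted p = 0.197 with an estimated correlation), with SQSTM1 at 1.40, PSAP at 0.85 and the cathepsin gene CTSL at 0.77. Of 27 p53 targets 12 rose, 0 fell and 15 did not pass (13 and 0 adjusted over the list alone, adjusted p = 9.03e-05, adjusted p = 0.43 with an estimated correlation). GDF15 (1.72), CDKN1B (1.17) and the proapoptotic gene BAX (0.94) rose. Of 23 apoptosis regulators 10 rose, 3 fell and 10 did not pass (11 and 3 adjusted over the list alone, adjusted p = 0.0409, adjusted p = 0.43 with an estimated correlation). Those that rose act in opposite directions: the initiator caspase gene CASP9 by 0.66 and the caspase inhibitor gene XIAP by 0.47. Of 22 cholesterol genes 10 rose, 0 fell and 12 did not pass (10 and 0 adjusted over the list alone, adjusted p = 7.01e-03, adjusted p = 0.197 with an estimated correlation), with TM7SF2 at 1.36, MSMO1 at 1.09 and INSIG1 at 0.66. Of 14 fatty acid synthesis genes 6 rose, 1 fell and 7 did not pass (7 and 1 adjusted over the list alone, adjusted p = 0.0393, adjusted p = 0.43 with an estimated correlation). The stearoyl-CoA desaturase gene SCD rose by 1.53, SREBF1 by 0.94 and ACACA by 0.56. Glycolysis and hypoxia genes did not pass as a list (5 rose, 1 fell and 21 did not pass, 2 and 1 adjusted over the list alone, adjusted p = 0.15, median 0.15).

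Hybridisation controls averaged 9.99 in RA 7-day samples and ACTB 3' minus 5' averaged 2.55, and 18S averaged 8.55 against 10.09 in undifferentiated samples. Of the 6097 genes, 276 changed by more than the largest exogenous control shift of 1.44 and 5821 by less. Within batch 2 alone 4861 genes passed and with batch as a random block 10056. Without RA 7-day replicate 1 4026 genes passed and without replicate 2 4025. Under other settings of scaling, probe set or blocking the cholesterol, fatty acid, Schwann and glial and apoptosis lists were lost, with adjusted p from 0.0687 to 0.208, 0.0718 to 0.299, 0.0528 to 0.228 and 0.0621 to 0.288, and the BDNF and MAP kinase list among genes above the median level (0.118). Averaged over all probe sets SREBF1 (0.15), ACACA (0.23) and CASP9 (0.21) did not pass, nor SNAP25 (0.62) and INSIG1 (0.35) without probe sets of the x and s suffix. Without a single sample 4 lists were lost: fatty acid synthesis (adjusted p = 0.152 without RA 7-day replicate 1, 0.0604 and 0.0556 without undifferentiated replicates 5 and 6), Schwann and glial (0.112 without RA 7-day replicate 2, 0.0832 without undifferentiated replicate 5), apoptosis (0.0951 without RA 7-day replicate 2, 0.227 without undifferentiated replicate 6) and neurofilament genes (0.0916 without undifferentiated replicate 6). ACACA did not pass without RA 7-day replicate 1 (adjusted p = 0.0871) or undifferentiated replicate 6 (0.133).

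Directly compared, RA 7-day and RA 4-day cells (2 against 4 samples) differed in 2 genes, with 1563 at an unadjusted p under 0.05. SIPA1L2, which encodes a RapGAP of synapses, was 1.11 ± 0.14 higher at 7 days (9.51 ± 0.10 against 8.40 ± 0.15, 2.16-fold, adjusted p = 0.0319). TCERG1L was 1.01 ± 0.10 higher (5.86 ± 0.13 against 4.86 ± 0.11, 2.01-fold, adjusted p = 0.00551). Next were HS3ST2 (1.07, adjusted p = 0.0573), CLSTN2 (0.88, 0.0917), CNKSR2 (1.39, 0.152), SCLT1 (-0.57, 0.0917), ADAM12 (-1.08, 0.148), SSUH2 (-0.70, 0.152), KIF14 (-0.62, 0.152) and VPS13A (-0.48, 0.152), which did not pass. The RA markers differed little: CYP26A1 by -0.02 ± 0.78, NTRK2 by 0.04 ± 0.12, RARB by 0.04 ± 0.10, RET by 0.01 ± 0.12 and DHRS3 by 0.13 ± 0.37. MKI67 differed by -0.05 ± 0.09 and TH by -0.02 ± 0.10. Without RA 7-day replicate 1 SIPA1L2 (adjusted p = 0.525) and TCERG1L (0.335) did not pass and the count was 0, while without RA 7-day replicate 2 it was 33. SSUH2 differed by -0.46 without RA 7-day replicate 1, and averaged over all probe sets TCERG1L differed by 0.53 (adjusted p = 0.101). SIPA1L2 did not pass either without undifferentiated replicates 1, 2, 3 or 4 (adjusted p = 0.0511, 0.0565, 0.0718 and 0.0534) or RA 4-day replicates 2, 3 or 4 (0.0967, 0.0638 and 0.0968), and within batch 2 alone 0 genes passed.

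**Figure D4:**
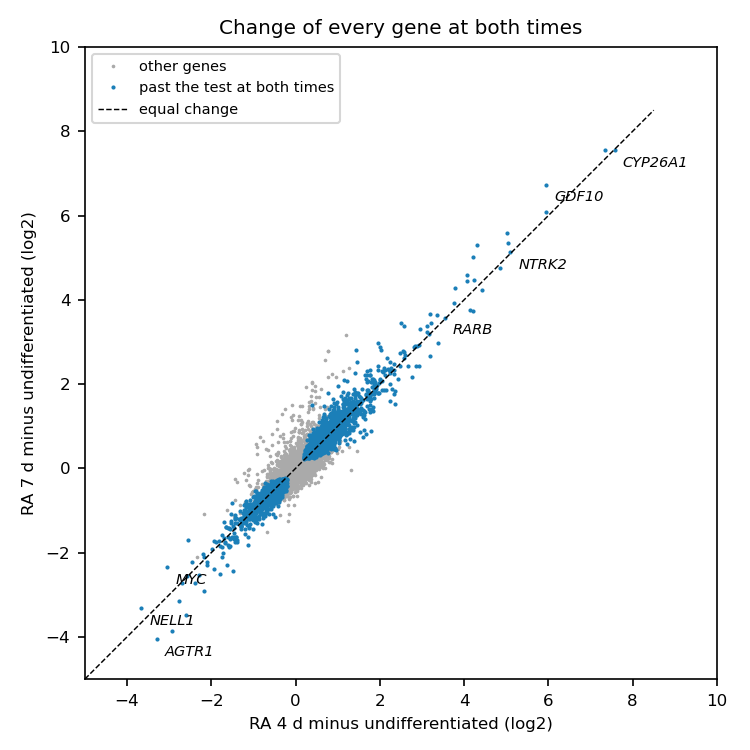
Log2 difference from undifferentiated cells of each of 18244 genes after 4 days (horizontal axis) and 7 days (vertical axis) of RA, with genes past the test at both times in blue, other genes in grey and a dashed line of equal change. CYP26A1 stood at 7.57 and 7.55, NTRK2 at 5.09 and 5.13 and AGTR1 at -3.29 and -4.06.

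Genes called at both times overlapped: 2654 were higher and 2475 lower at both, 0 in opposite directions, where independent lists of these sizes would share 558.6 and 575.4. Both comparisons used the same undifferentiated samples, which raises the overlap by itself. With undifferentiated samples split between the times, 2915 were shared higher and 2939 lower (846.6 and 1083 if independent). The split fits called 4283 genes higher and 4510 lower at the earlier time, against 3360 and 3426 in the main fit. At the later time they called 3606 and 4381, against 3033 and 3064. The split fits also had no batch term, unlike the main fit. Leaving it out with all samples kept gave 10153 and 9087 calls at the earlier and later time. With another model, longer lists and fewer samples, these shared counts cannot be compared with those above. Nor were the split samples shown to be independent, as the batches had nearly the same mean at every probe set. How much overlap the shared samples caused was therefore left open. In 20 simulated draws with no effect at most 0 calls were shared, which says little, because almost no gene passes the test without an effect. The draws held independent noise without differences between arrays. They show only how far shared undifferentiated samples raise the correlation and covariance. Across genes, which are not independent replicates, the fold changes had r = 0.934 against 0.575 simulated with no effect, and a covariance of 0.220 against 0.0113.

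As groups, 10 lists shifted between 4 and 7 days by small amounts, though 0 members of any of them passed over all genes. Glycolysis and hypoxia genes were lower at 7 days, 26 of 27 with a negative difference and a median of -0.22 (adjusted p = 2.05e-08, adjusted p = 0.43 with an estimated correlation, 0 past the test adjusted over the list alone). BNIP3 differed by -0.44 and LDHA by -0.33. G2 and mitosis genes were lower (median -0.12, adjusted p = 5.48e-06, adjusted p = 0.43 with an estimated correlation), and 5 of 43 were lower adjusted over the list alone. CENPF differed by -0.55 and CENPE by -0.70. All 23 noradrenergic transcription factors had a negative difference (median -0.20, adjusted p = 2.86e-03, adjusted p = 0.43 with an estimated correlation, 0 adjusted over the list alone). Higher at 7 days were p53 targets (median 0.20, 24 of 27 above 0, adjusted p = 1.24e-06, adjusted p = 0.334 with an estimated correlation, 2 adjusted over the list alone), with BAX at 0.53 and GDF15 at 0.65. Interferon-stimulated genes were higher (adjusted p = 1.43e-04, adjusted p = 0.13 with an estimated correlation), 5 of 33 adjusted over the list alone. TAP1 differed by 1.26 and PSMB8 by 0.98.

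Further upward shifts were found at 7 days for lysosome genes (24 of 29 above 0, adjusted p = 1.58e-04, adjusted p = 0.43 with an estimated correlation) and oxidative stress genes (23 of 32 above 0, adjusted p = 3.23e-04, adjusted p = 0.43 with an estimated correlation). The same held for ribosome biogenesis (26 of 37 above 0, adjusted p = 6.44e-03, adjusted p = 0.568 with an estimated correlation) and fatty acid synthesis genes (11 of 14 above 0, adjusted p = 0.0323, adjusted p = 0.43 with an estimated correlation). Mesenchymal-type genes (18 of 32 above 0, adjusted p = 7.01e-03, adjusted p = 0.456 with an estimated correlation) included COL3A1 at 1.62 and CD44 at 1.65. In these 5 lists 0 members passed adjusted over the list alone. Without RA 7-day replicate 1 the fatty acid (adjusted p = 0.59), noradrenergic (0.369) and mesenchymal (0.281) lists did not pass and the ribosome list turned to the other side of 0 (0.713). Without replicate 2 the lysosome list did not pass (0.384), and without RA 4-day replicate 3 the fatty acid list (0.0992). Under other settings of scaling, probe set, level or covariate the fatty acid, noradrenergic, ribosome and mesenchymal lists were lost, with adjusted p between 0.0579 and 0.601. The covariate was the mean of the mesenchymal-type list itself, so a loss of that list under it would be set in advance.

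RA plus BDNF was compared with undifferentiated cells (1 against 6 samples). The calls below take their spread from the other groups and describe that 1 sample. CYP26A1 (7.69 ± 1.1, 206-fold, adjusted p = 7.01e-04), CYP26B1 (7.44 ± 1.08), GDF10 (6.60 ± 0.22, 96.8-fold), DHRS3 (6.08 ± 0.53), POU2AF2 (5.68 ± 0.43) and ENPP2 (5.40 ± 0.32), which encodes the lysophospholipase autotaxin, rose most. NTRK2 rose by 5.07 ± 0.16, RARB by 3.50 ± 0.14 and RET by 2.44 ± 0.17. AGTR1 (-3.94 ± 0.29), MYC (-3.75 ± 0.55, 13.4-fold, adjusted p = 8.27e-04), LMO4 (-3.60 ± 0.31), SLITRK6 (-3.32 ± 0.27), NELL1 (-3.22 ± 0.44) and SOX6 (-3.22 ± 0.23) fell most. MKI67 (0.00 ± 0.13, adjusted p = 0.991) and TH (0.06 ± 0.15, adjusted p = 0.848) did not pass. In all 2561 genes (14%) passed, 1560 higher and 1001 lower, 617 over 2-fold. Hybridisation controls averaged 10.02, 18S 8.78 and ACTB 3' minus 5' 2.26, and 1010 genes changed by more than the largest exogenous control shift of 0.81 and 1551 by less. Within batch 2 alone 1710 genes passed, without a batch term 4266 and with batch as a random block 4760. With probe sets of the x and s suffix left out NELL1 differed by -0.00 (adjusted p = 0.993) and LMO4 by -1.30. Without undifferentiated replicate 5 and without replicate 6 the differences were 6.08 and 9.30 for CYP26A1, 5.71 and 9.16 for CYP26B1, 5.19 and 6.97 for DHRS3, and 4.97 and 6.40 for POU2AF2. Averaged over all probe sets the difference was 3.83 for CYP26B1, 3.46 for DHRS3, 2.51 for NTRK2, -2.03 for NELL1 and -1.11 for SOX6.

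In the RA plus BDNF sample 13 of 25 RA targets rose, 0 fell and 12 did not pass (14 and 1 adjusted over the list alone, adjusted p = 7.51e-09, adjusted p = 0.0347 with an estimated correlation). Of 37 ribosome biogenesis and MYC targets 0 rose, 28 fell and 9 did not pass (0 and 34 adjusted over the list alone, adjusted p = 2.26e-19, adjusted p = 0.197 with an estimated correlation), with NOP16 at -1.73, BYSL at -1.64 and WDR12 at -1.17. Of 43 G2 and mitosis genes 0 rose, 9 fell and 34 did not pass (0 and 13 adjusted over the list alone, adjusted p = 1.24e-06, adjusted p = 0.43 with an estimated correlation), with CDC20 at -1.15, the checkpoint kinase gene BUB1B at -0.71 and CKS2 at -0.61. Of 33 oxidative phosphorylation genes 0 rose, 3 fell and 30 did not pass (0 and 1 adjusted over the list alone, adjusted p = 0.0409, adjusted p = 0.509 with an estimated correlation): NDUFV1 (-0.62), NDUFS1 (-0.46) and ATP5F1C (-0.44).

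Of 37 synaptic vesicle genes 9 rose with RA plus BDNF, 0 fell and 28 did not pass (12 and 0 adjusted over the list alone, adjusted p = 5.89e-04, adjusted p = 0.43 with an estimated correlation), with SYNGR3 at 1.25, PCLO at 1.14 and SNAP25 at 1.12. Of 27 dense core granule genes 7 rose, 0 fell and 20 did not pass (12 and 0 adjusted over the list alone, adjusted p = 9.11e-05, adjusted p = 0.13 with an estimated correlation), with CHGB at 2.53, GAL at 1.77 and VGF at 1.35. Of 41 neurofilament and growth cone genes 9 rose, 2 fell and 30 did not pass (13 and 3 adjusted over the list alone, adjusted p = 7.01e-03, adjusted p = 0.606 with an estimated correlation), with DPYSL3 at 2.79 (3.43 or 2.15 without undifferentiated replicate 5 or 6), ENO2 at 1.05 and NCAM1 at 0.63. Of 27 catecholamine neuron genes 7 rose, 0 fell and 20 did not pass (8 and 0 adjusted over the list alone, adjusted p = 0.0443, adjusted p = 0.278 with an estimated correlation). The vesicular monoamine transporter gene SLC18A1 rose by 2.27, DBH, which converts dopamine to noradrenaline, by 1.21 and GCH1 by 1.08. Of 18 neurotrophin and GDNF family genes 4 rose, 0 fell and 14 did not pass (5 and 1 adjusted over the list alone, adjusted p = 0.0212, adjusted p = 0.432 with an estimated correlation), including SHC1 (0.45). Of 35 BDNF and MAP kinase responsive genes 8 rose, 1 fell and 26 did not pass (8 and 1 adjusted over the list alone, adjusted p = 4.69e-03, adjusted p = 0.456 with an estimated correlation), with INHBA at 1.82 and DUSP6 at 1.70.

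Of 29 lysosome and autophagy genes 14 rose with RA plus BDNF, 0 fell and 15 did not pass (16 and 0 adjusted over the list alone, adjusted p = 2.05e-08, adjusted p = 0.197 with an estimated correlation), with GABARAPL1 at 1.12, CTSF at 1.00 and SQSTM1 at 0.94. Of 27 p53 targets 7 rose, 0 fell and 20 did not pass (8 and 0 adjusted over the list alone, adjusted p = 3.12e-04, adjusted p = 0.43 with an estimated correlation), with GDF15 at 2.02, CDKN1B at 1.41 and BTG1 at 0.86. Of 27 glycolysis and hypoxia genes 5 rose, 1 fell and 21 did not pass (5 and 1 adjusted over the list alone, adjusted p = 1.26e-03, adjusted p = 0.548 with an estimated correlation), with P4HA2 at 1.30, P4HA1 at 0.71 and VEGFA at 0.66. Of 24 HOX genes 6 rose, 0 fell and 18 did not pass (6 and 0 adjusted over the list alone, adjusted p = 0.0445, adjusted p = 0.493 with an estimated correlation), with HOXD8 at 2.09, HOXD9 at 1.97 and HOXD3 at 1.40.

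After 7 days of RA alone the HOX and neurotrophin lists did not pass (camera adjusted p = 0.141 and 0.263), yet they had moved by similar amounts. Against undifferentiated cells the HOX mean was 0.37 after RA and 0.36 with RA plus BDNF, and the neurotrophin mean 0.53 and 0.60. Between RA plus BDNF and RA 7 days the HOX mean differed by -0.01. These list calls are thus no sign of a BDNF effect. Several of the RA plus BDNF calls rested on single undifferentiated samples or single probe sets. Without undifferentiated replicate 6 the neurofilament (adjusted p = 0.547), HOX (0.153), BDNF and MAP kinase (0.0821) and oxidative phosphorylation (0.0821) lists and VEGFA (0.0789) did not pass. Without replicate 5 the catecholamine (0.0912), neurotrophin (0.0657) and oxidative phosphorylation (0.0604) lists did not, nor the catecholamine list without replicate 1 (0.0519), the HOX list without RA 4-day replicate 1 (0.0588) or RA 7-day replicate 1 (0.05), or oxidative phosphorylation without RA 7-day replicate 1 (0.0536). NDUFS1 did not pass when any of 9 other samples was left out, with adjusted p between 0.054 and 0.174, nor did ATP5F1C when any of 9 was, between 0.0512 and 0.0989. Under other settings, batch 2 alone among them, the catecholamine and oxidative phosphorylation lists were lost with adjusted p from 0.051 to 0.0916 and 0.051 to 0.61, and without probe sets of the x and s suffix the glycolysis list was (0.0638). With probe sets of the x and s suffix left out BTG1 differed by -0.24, VEGFA by -0.11 and GABARAPL1 by -0.05, and SNAP25 (0.89), SHC1 (0.65) and SQSTM1 (0.49) did not pass.

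The effect of BDNF beyond RA was addressed by RA plus BDNF against RA 7 days (1 against 2 samples). With limma 0 of 18244 genes passed, 1225 had an unadjusted p under 0.05, the smallest adjusted p was 0.695, and robust variance moderation and the other settings below also gave 0, leaving out single samples aside. The median SE of a difference was 0.16. The largest moderated t values were for RASSF7 (0.57 ± 0.13), ZMAT5 (0.43 ± 0.10), ARHGAP45 (0.60 ± 0.14), PRAP1 (0.53 ± 0.12) and PLCXD3 (0.50 ± 0.12) on the higher side. On the lower side they were for TRAF3 (-0.71 ± 0.13), TCERG1L (-0.76 ± 0.15), PLAT (-1.26 ± 0.26), ZBTB8A (-0.70 ± 0.15) and GLE1 (-0.60 ± 0.13). NTRK2, the BDNF receptor gene, differed by -0.06 ± 0.16, RARB by -0.08 ± 0.14, CYP26A1 by 0.14 ± 1.1, RET by 0.10 ± 0.17, DHRS3 by -0.00 ± 0.53, MKI67 by -0.09 ± 0.13 and TH by 0.12 ± 0.15. The BDNF and MAP kinase responsive genes did not pass as a list (14 of 35 above 0, adjusted p = 0.228), and VGF differed by 0.08, ARC by 0.74 and EGR3 by 1.23. Without RA 7-day replicate 2 the count was 5.

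The list shifts between RA plus BDNF and RA 7 days rest on 1 sample without a spread of its own, so they do not separate BDNF from other features of that culture. The largest exogenous control shift in this comparison was 1.45, more than any gene difference named below, though hybridisation controls shifted by 0.04 on average. ACTB 3' minus 5' was 2.26 with RA plus BDNF and 2.55 at 7 days, and 28S ribosomal RNA 8.71 and 7.96. In it 41 of 45 DNA replication genes had a negative difference from RA 7 days (median -0.22, adjusted p = 9.92e-07, adjusted p = 0.548 with an estimated correlation), with RRM1 at -0.43 and MCM6 at -0.38. So had 35 of 37 ribosome biogenesis and MYC targets (median -0.18, adjusted p = 9.92e-07, adjusted p = 0.43 with an estimated correlation), with MYC at -1.40. The mean of this list was 8.17 and 7.95 in RA 7-day replicates 1 and 2 and 7.84 in the RA plus BDNF sample, so it lay nearer replicate 2. The DNA replication list averaged 8.38 and 8.36 in these replicates and 8.175 with RA plus BDNF. Among undifferentiated samples alone it ran from 8.08 to 8.497, a wider range than that shift. Of 27 glycolysis and hypoxia genes 25 were above 0 (median 0.17, adjusted p = 1.34e-03, adjusted p = 0.548 with an estimated correlation), with VEGFA at 0.48. The lists of fatty acid synthesis (adjusted p = 0.0122, adjusted p = 0.43 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.0149, adjusted p = 0.266 with an estimated correlation) were lower, with 2 of 14 and 7 of 22 members above 0. Also lower were oxidative stress (adjusted p = 0.0206, adjusted p = 0.51 with an estimated correlation), unfolded protein response (adjusted p = 0.03, adjusted p = 0.615 with an estimated correlation) and G2 and mitosis genes (adjusted p = 0.0409, adjusted p = 0.623 with an estimated correlation), with 11 of 32, 10 of 30 and 16 of 43 above 0. In all 8 lists 0 members passed, over all genes or adjusted over the list alone. Under other settings of scaling, probe set or level the last 5 were lost, with adjusted p between 0.051 and 0.604. Without RA 7-day replicate 1 the fatty acid (0.209), unfolded protein (0.221), oxidative stress (0.093) and G2 and mitosis (0.545) lists did not pass, nor the last without RA 4-day replicate 2 (0.0511).

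The batch term itself could be tested in undifferentiated cells alone, 4 samples against 2. With limma 0 genes passed and 0 had an unadjusted p under 0.05, where chance alone would give such p-values, so the test says nothing about the batches. The means of the batches differed with an SD of 0.0175 over probe sets, against 0.0924 to 0.175 for the other 14 ways to part 2 of the 6 samples from 4. The deviations of undifferentiated replicates 5 and 6 from the others had r = -0.977 across probe sets.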

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

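Of the tests that weigh explanations in this part, only the splits of the RA 4-day and undifferentiated samples into random groups were set before the result was seen, and all the others were chosen after it.

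The genes past the test at 4 days went with differences between arrays in control probe sets, so a treatment effect was weighed against such differences. Regrouping the 10 samples at random gave a count as large as the 6617 of the true grouping in 1 of 100 splits, the true one itself. The highest other count was 1, which argues against an accidental grouping only. The other splits mixed treated and undifferentiated samples, so any difference carried by all RA 4-day arrays would give the same outcome. They also crossed the 2 batches, though all RA 4-day samples lay in batch 2. A difference between arrays that follows the signal level would be removed by cyclic loess, but 5260 of 6786 calls (77.5%) were kept in the same direction, so it does not account for most of them. A difference carried by every treated array and unrelated to signal level cannot be told apart from the treatment for the 6630 genes that changed by less than the largest exogenous control shift of 1.69. The 156 genes beyond it, among them CYP26A1, NTRK2, RARB and MYC, changed by more than any exogenous control. Their slopes on ACTB 3' minus 5' or on 18S were taken between samples of the same treated group. These slopes covered a median share of at most 0.0588 of the change, whichever sample was left out. The shares were signed, so those of opposite sign could offset each other, and the genes had been picked for large changes. The small median therefore argues only against a graded quality loss between treated samples behind most of the change in most of these genes. The slopes came from 4 RA 4-day and 2 RA 7-day samples. No treated array (ACTB 2.22 or more) reached the undifferentiated range (up to 1.97). A quality difference shared by all treated arrays, or one acting on single genes, was therefore not excluded.

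The batches of undifferentiated samples had nearly the same mean at every probe set. The SD of the difference of the batch means was 0.0175, which could come from an adjustment of each probe set for batch before the values were made public, and the lowest SD of the other ways to part 2 of 6 samples from 4 was 0.0924, which rules out batches that had merely never differed. A first version of the test on unadjusted batches asked for r below -0.5 in the batch 2 pair and above 0 in all other pairs, and stayed undecided with r of -0.977 in that pair and -0.22 to 0.50 in the others. No biological explanation was tested.

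Mesenchymal-type genes averaged 7.11 in RA 7-day replicate 1, 6.73 in replicate 2, 6.60 with RA plus BDNF and 6.62 after 4 days. If replicate 1 alone stood high, replicate 2 would lie near the other groups. It exceeded the RA 4-day mean by 0.12, against 0.49 for replicate 1, so a single high sample could account for the rise from 4 to 7 days. Whether that sample held more mesenchymal-type cells was not tested. The mean of the RA plus BDNF sample lay -0.13 from replicate 2 and -0.51 from replicate 1, which left open whether BDNF lowered these genes. The median over members was -0.085 and -0.01, with 16 of 32 members lower in each case. The differences in the mean thus came from part of the list. A further test by the list as a whole (adjusted p = 0.606 with an estimated correlation) was undecided and was dropped when the wording of this pattern was changed.

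Single samples stood far from the rest of their group in 14 of 270 values tested, 4 in undifferentiated and 10 in RA 4-day samples, where chance alone gives about 1 in 20. RA 4-day replicate 1 held 7 of them. It also had the highest 3' minus 5' signal of ACTB (3.25) and GAPDH (1.16) of any array and the lowest 18S (6.49). Its NGFR was 4.74 (others 4.98 to 4.99), SQSTM1 10.1 (9.67 to 9.72), STARD4 6.07 (6.51 to 6.59), WDR43 6.44 (6.2) and ATP5F1C 8.86 (9.03 to 9.07). The list means of its apoptosis regulators and Parkinson disease genes were 7.32 (others 7.25 to 7.26) and 7.91 (7.83 to 7.84). In RA 4-day replicate 4 GDF15 was 9.19 (9.46 to 9.48) and POU2AF2 8.34 (8.51 to 8.54), and in replicate 2 WDR12 was 7.63 (7.86 to 7.88). In undifferentiated replicate 4 GABARAPL1 was 5.36 (5.68 to 5.82). In undifferentiated replicate 3 SYN1 was 6.01 (5.97 to 5.98), and the means of noradrenergic transcription factors and Wnt pathway genes were 8.96 (9.11 to 9.16) and 5.6 (5.64 to 5.65).

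The effect of RA against undifferentiated cells differed between 7 and 4 days in SIPA1L2 (by 1.11) and TCERG1L (by 1.01), by limma's test of the difference itself. With the undifferentiated samples in common this is the same contrast as RA 7 against 4 days, and without RA 7-day replicate 1 neither gene passed (adjusted p = 0.525 and 0.335).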

How the results depend on the processing

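Cyclic loess, the mesenchymal covariate, the split of controls and the leaving out of samples for lists were added after the data were seen. Leaving out single samples aside, counts against undifferentiated cells kept to within 1.5 times of 6786, 6097 and 2561 except as follows. With batch as a random block (correlation -0.115) they were 11465, 10056 and 4760, and without a batch term RA plus BDNF gave 4266. In both, batch 1 undifferentiated samples also entered the contrast. The median fold change over genes at 4 days hardly moved (-0.0458 in the main fit, -0.0451 without a batch term, -0.045 with the block). All main calls were kept. If the values had been adjusted for batch beforehand, batch 1 adds nothing on the size of the contrast, and these counts may be too high. Genes above the median level (9122 tested) gave 4498 (2873 higher, 1625 lower) and 4004 (2628 and 1376) for RA, and every probe set on its own 13190 and 11465, as fewer genes or more probe sets were tested. RA 7 against 4 days gave 2, and 5 without a batch term, 0 in batch 2 arrays only, 5 with the random batch block, 12 with every array as a sample (correlation 0.406), 20 with the first array only, 1 above the median level, 1 with every probe set and 0 with the mesenchymal covariate; the cause was not tested. RA plus BDNF against RA 7 days gave 0 under every setting that kept all samples. Within batch 2 alone 5669, 4861 and 1710 genes passed against undifferentiated cells, and after cyclic loess 5924, 5212 and 2494. Quantile normalization again kept 79.5%, 75.6% and 86.1% of the calls against undifferentiated cells. At 7 days 3303 genes were higher and 2406 lower after centring on the median, and 2363 and 3117 after quantile normalization again, against 3033 and 3064. No scaling turned the fold change of a called gene.

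Replicate numbers showed no pairing of undifferentiated and RA 4-day samples, which lay in different batches. Same-numbered deviations had r of -0.05 to 0.14, and 0 of 4 undifferentiated and 1 of 4 RA 4-day samples correlated best with their own number. Same-numbered r was 0.128 between RA 4-day and RA 7-day samples and 0.092 between undifferentiated and RA 7-day samples. The r of -0.128 and -0.092 between differing numbers there was set in advance, as each group was centred on 2 samples. Pairing with RA 7-day samples was thus left undecided. A random replicate block (correlation 0.031) gave 6772, 6082, 2555, 2 and 0 genes, a fixed replicate block in place of batch 9201 and 6974 for RA at 4 and 7 days, and a fixed replicate block on replicates 1 and 2 of both RA groups 51.

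Leaving out single samples, the counts ranged from 5431 to 6746 (RA 4 days), 4025 to 6405 (RA 7 days), 2219 to 2701 (RA plus BDNF), 0 to 33 (7 against 4 days), 0 to 5 (BDNF against RA 7 days) and 0 to 5 (batches). Fewer samples account for part of this. Lists past camera's test ranged from 48 to 60 against 56 (38 up, 18 down). With the correlation between genes estimated, 3 passed. The ribosome biogenesis and MYC target median for 7 against 4 days went from -1.49e-04 without RA 7-day replicate 1 to 0.14 without replicate 2; the cause was not tested.

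The choice of probe set turned the sign of 9 named results, several of them to values near 0, and the cause was not tested. With the mean of all probe sets KIF1A differed by -0.11 at 4 days and -0.0788 at 7 days. With x and s suffix probe sets left out NELL1 differed by 0.0631 and 0.00403, GFAP by 0.0356 and 0.0697, and with RA plus BDNF BTG1 by -0.24, VEGFA by -0.11 and GABARAPL1 by -0.0482. Probe sets that passed on their own disagreed in sign in 2 of 94 pairs of named gene and comparison, both KIF1A. Those of NELL1 (3 of 4) and GFAP (2 of 8) were all lower at 4 days. Those of VEGFA (4 of 10) and BTG1 (2 of 3) were all higher with RA plus BDNF. Signal over background limits weakly expressed genes, whose fold changes are compressed. The values of CYP26A1 in undifferentiated cells spread from 3.30 to 6.52, so its fold change is imprecise, and the cause was not tested.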

Other observations

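Of the tests in this part, all were gene list and gene tests fixed before the data were seen, and the choice of genes to print from them was made after. Lists without a shift as a whole held strong changes in both directions at 4 days of RA. Of all 18244 genes 37.2% passed at 4 days, 3360 higher and 3426 lower, so most lists would hold members on both sides. Changes below the largest exogenous control shift of 1.69 cannot be told apart from a difference carried by every treated array. Of 24 HOX genes 8 rose, 3 fell and 13 did not pass (8 and 3 adjusted over the list alone, adjusted p = 0.304), those that rose all in the HOXC and HOXD clusters. HOXD8 (2.13), HOXD9 (1.84), HOXD3 (1.58) and HOXC8 (1.18) rose, while HOXB3 (-0.52), HOXB8 (-0.52) and HOXD10 (-0.34) fell. Of 27 catecholamine neuron genes 9 rose, 2 fell and 16 did not pass (9 and 2 adjusted over the list alone, adjusted p = 0.113). SLC18A1 (1.95), the monoamine oxidase gene MAOB (1.41), GCH1 (1.11) and DBH (0.88) rose, ADRA2A fell by 0.96 and TH differed by -0.04. Of 21 cholinergic genes 5 rose, 2 fell and 14 did not pass (5 and 2 adjusted over the list alone, adjusted p = 0.533). The muscarinic receptor gene CHRM3 (2.2) and the nicotinic subunit gene CHRNA3 (0.96) rose, and CHAT, which makes acetylcholine, fell by 0.65. Of 23 noradrenergic transcription factors 3 rose, 6 fell and 14 did not pass (3 and 6 adjusted over the list alone, adjusted p = 0.894), with PHOX2A at 0.72, ID4 at -1.56, INSM2 at -1.40, MYCN at -0.96 and GATA3 at -0.55. Of 32 mesenchymal-type genes 7 rose, 7 fell and 18 did not pass (7 and 7 adjusted over the list alone, adjusted p = 0.732), with TIMP1 at 1.03 and VIM, which encodes vimentin, at -1.20.

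Genes of neuronal wiring changed individually at 4 days. Of 41 axon guidance genes 9 rose, 14 fell and 18 did not pass (9 and 15 adjusted over the list alone, adjusted p = 0.452): SEMA3A (1.69) and SLIT2 (1.55) rose, SEMA3C (-2.30) and the netrin receptor genes UNC5A (-1.61) and UNC5D (-1.30) fell. Of 31 postsynaptic and adhesion genes 6 rose, 6 fell and 19 did not pass (6 and 9 adjusted over the list alone, adjusted p = 0.978), with the scaffold gene DLG2 at 4.23, the kainate receptor gene GRIK2 at 1.33 and SHANK3 at -0.92. Of 33 ion channel genes 7 rose, 6 fell and 20 did not pass (7 and 6 adjusted over the list alone, adjusted p = 0.97), with the sodium channel genes SCN3A at 1.78 and SCN2A at 1.03 and the potassium channel gene KCNMA1 at -1.44. Of 18 neurotrophin and GDNF family genes 5 rose, 4 fell and 9 did not pass (5 and 4 adjusted over the list alone, adjusted p = 0.336). Of 27 Wnt pathway genes 10 rose, 5 fell and 12 did not pass (10 and 5 adjusted over the list alone, adjusted p = 0.463), and DKK2 (4.84), FRZB (1.30) and DKK3 (0.85) rose. Of 21 Notch genes 4 rose, 7 fell and 10 did not pass (4 and 8 adjusted over the list alone, adjusted p = 0.526): HES1 (1.88) and HEY1 (1.39) rose, NOTCH1 (-0.91) and DLL3 (-0.82) fell.

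Stress response genes changed in both directions at 4 days, as did genes at large (37.2% past the test, 3360 higher and 3426 lower). The limit on changes below 1.69 given above holds here too. Of 30 unfolded protein and integrated stress response genes 7 rose, 10 fell and 13 did not pass (7 and 10 adjusted over the list alone, adjusted p = 0.475). As examples chosen after the data were seen, the chaperone gene HSPA5 (1.05), CRELD2 (0.82) and HYOU1 (0.70) rose, while ATF4 (-0.82) and its targets TRIB3 (-1.23), MTHFD2 (-1.05) and ASNS (-0.66) fell. Of 32 oxidative stress genes 4 rose, 10 fell and 18 did not pass (5 and 10 adjusted over the list alone, adjusted p = 0.999), with the glutathione peroxidase genes GPX3 at 2.26 and GPX1 at -0.60. Of 33 oxidative phosphorylation genes 4 rose, 10 fell and 19 did not pass (4 and 10 adjusted over the list alone, adjusted p = 0.166), with NDUFV1 at -0.68. Of 23 apoptosis regulators 10 rose, 3 fell and 10 did not pass (11 and 3 adjusted over the list alone, adjusted p = 0.111), with BCL2 at 0.60 and BID at -1.74. Of 33 interferon-stimulated genes 5 rose, 5 fell and 23 did not pass (5 and 5 adjusted over the list alone, adjusted p = 0.952), with IRF9 at 1.41 and ISG15 at -0.70. Of 34 immediate early genes 3 rose, 5 fell and 26 did not pass (2 and 2 adjusted over the list alone, adjusted p = 0.952), with KLF2 at 1.47 and NR4A3 at -2.59. Of 19 Parkinson disease genes 6 rose, 3 fell and 10 did not pass (6 and 3 adjusted over the list alone, adjusted p = 0.137), with FBXO7 at 0.67 and the tau gene MAPT at 0.55. Of 14 fatty acid synthesis genes 5 rose, 2 fell and 7 did not pass (6 and 2 adjusted over the list alone, adjusted p = 0.147).

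In 33 of the 160 list tests the median, the mean and the test differed in sign, and 0 of these passed camera's test. At 4 days they included HOX (median -0.07, mean 0.29), Wnt (-0.09, 0.31) and postsynaptic genes (-0.16, 0.14), with 11 of 24, 12 of 27 and 13 of 31 members above 0.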
